A study of Schizosaccharomyces pombe with 24 samples.

How the data were processed

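RNA was measured by sequencing in fission yeast (Schizosaccharomyces pombe) of 2 strains, a wild type (wt) and a strain labelled clr4D, in which the gene for the histone H3 lysine 9 methyltransferase Clr4 is given as deleted. Both are labelled with the same h+ (P mating type) background. Cells grew at 32 °C in supplemented minimal medium, were moved to the same medium without nitrogen, and were sampled at 0, 1, 2, 4, 10 and 24 h. The 2 strains, 6 times and 2 replicates give 12 groups and 24 libraries, and the series description calls the replicates biological. Per the labels, RNA was extracted with hot phenol, treated with DNase I, depleted of ribosomal RNA and made into directional libraries.

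The deposited values are counts of reads per annotated feature. According to the submitters' processing notes, the authors aligned reads with TopHat2 2.0.8 to the ASM294v2 genome and counted them with HTSeq 0.6.1. The strand setting of the counting and the annotation release are not given in the sources used here. Each library listed 6878 features, which became 6877 genes after the counts of transcripts of the same gene were summed. Of these, 6705 were matched by systematic name to a reference annotation of another build, ASM294v3, and 172 were not. That annotation served for gene names, gene class and neighbours only, so no positions are printed. It classes 5103 of the genes as protein coding, 1382 as long non-coding RNA (lncRNA) and 171 as tRNA. The 5 HTSeq totals for reads without a gene were used for quality only.

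Reads on genes ranged from 637723 to 4427020 per library with a median of 1436782. Reads aligned to more than 1 place made up 5.43% to 12.37% of each library and were not counted for any gene, which limits what can be said about repeats and near-identical copies. Reads outside features made up 2.09% to 5.14%, and ambiguous reads 0.95% to 1.41%. Protein-coding genes held 96.94% to 98.73% of gene reads, and 5638 to 6306 genes had a read. A count of 0 allows up to 3 reads, which is 0.68 to 4.7 CPM (read counts scaled to a common library total) per library. For a group of 2 libraries the limit is 3 reads over the group, which is 0.53 to 1.97 CPM. These limits cover counting error only, because reads without molecular identifiers are not independent molecules.

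Genes with low counts were removed with the default filter of edgeR (filterByExpr), which kept 5664 genes (4944 coding and 675 lncRNA) and left out 1213. Libraries were scaled by the trimmed mean of M values (TMM), with factors from 0.695 to 1.263. A quasi-likelihood negative binomial model with 12 group means was fitted in edgeR 4.0.16 (R 4.3.3) with robust dispersion estimates. The common biological coefficient of variation was 0.122, with 12 residual and a median of 11.4 prior degrees of freedom. Tests were two-sided quasi-likelihood F tests, adjusted by Benjamini-Hochberg over all tested genes within each comparison. A gene is called where the adjusted p lies under 0.05. Standard errors (SE) of log2 differences are the difference divided by the square root of F. Levels are mean CPM ± SD of 2 libraries, scaled by TMM.

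The comparisons were clr4D against wt at each time and over the mean of the 6 times, each later time against 0 h within each strain, the difference between the strains in the change from 0 h to 24 h, and an F test of any difference between the strains in the course over time. Lists of genes written from general knowledge were tested with camera in limma 3.58.1 on log2 CPM (prior count 2), with a preset correlation of 0.01 between members and again with an estimated correlation. The 24 lists were heterochromatin and RNAi factors, subtelomeric genes, M-cell mating genes, P-cell mating genes, pheromone response and conjugation, early meiosis and recombination, middle and late meiosis and sporulation, nitrogen starvation induced genes, autophagy, cytosolic ribosomal proteins, ribosome biogenesis, core environmental stress response, histones, S phase MBF targets, mitosis, Tf2 retrotransposons, wtf genes, iron uptake, phosphate response, proteasome, glycolysis, amino acid biosynthesis, kinetochore and mitochondrially encoded genes. The last list matched 0 genes, which left 23 lists and 414 list tests over 18 comparisons. The Tf2 list matched only after letter case was ignored, a change made after the names were seen.

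The genes named in the text follow a rule. It takes clr4; from each of 6 comparisons the 10 largest rises and the 10 largest falls among called genes with at least 10 CPM in the higher group and no overlap between the libraries of the groups; from each list the 2 largest rises and falls among called members, or else the 2 members with the highest level; and a set of landmark genes (among them swi6, tlh1, tlh2, ste11, mei2, mei3, mei4, mfm1, mam2, map2, map3, isp6, fnx1, atg8, hsp9, cdc22 and fbp1). The condition of no overlap applied only where 2 groups were compared. It was not used for the mean of the 6 times or for the strain difference in the change from 0 h to 24 h. The groups, comparisons, lists, threshold, alternatives and this rule were chosen before the data were examined. Genes named outside the rule are said to be so where they appear.

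Alternatives were the size factors of DESeq2, upper quartile scaling and scaling by library totals alone; no filter and a stricter filter of 10 CPM in 2 libraries; protein-coding genes only; the fry set test in place of camera, which asks whether a list's genes move and compares them with no other genes; DESeq2 1.42.0 and limma-voom in place of edgeR; a model of the compared groups alone; a replicate block; and each library left out in turn. After the data were seen, a fit without wt 0 h replicate 2 and wt 4 h replicate 2 was added. The pipeline was tested on simulated data. Of 50 genes per size, 40% of simulated changes of 1.5-fold were called, 76% of 2-fold, 94% of 4-fold and 98% of 8-fold, and 5 of 159 calls were false. The changes were placed only in clr4D 24 h against wt 24 h. Counts were drawn from the fitted model, with independent libraries and the same spread per gene in all groups. These rates therefore do not cover groups that vary more or replicates that share something. Detection may be lower where libraries are shallower. The labels do not say whether equal replicate numbers share anything. The 66 correlations of replicate deviations between groups ran from -0.077 to 0.333, and 23 lay above 0.1, so a weak pairing is not excluded, and the block is kept as an alternative only. With 2 replicates per group, the p-values rest on a spread per gene shared by the 12 groups, not on the compared libraries alone. Replicates of wt 4 h lay further apart, with a chi-square per degree of freedom of 20.19, against 2.19 to 5.89 in the other groups. For comparisons with wt 4 h the shared spread may therefore be too small. Independence of the replicates is known only as far as the labels describe them. Small RNA and chromatin data were not analysed here.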

Results

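The series measured RNA levels by directional RNA sequencing in fission yeast moved to medium without nitrogen, in wild-type cells and in cells labelled as lacking Clr4, the enzyme that methylates histone H3 at lysine 9 in heterochromatin. Each strain has 2 libraries at each of 0, 1, 2, 4, 10 and 24 h. The stated purpose is to compare the strains during nitrogen starvation. Depth in wt ran from 637723 gene reads (4 h, replicate 2) to 4427020 (4 h, replicate 1), and in clr4D-labelled libraries from 638879 (0 h, replicate 2) to 1807900 (24 h, replicate 2). The 2 libraries of a group correlated across genes at a Pearson r of 0.9595 to 0.9905, lowest at wt 4 h. In that group, replicate 2 had a median ribosomal protein level of 9.37 on the log2 CPM scale against 8.18 in replicate 1, and a median glycolysis level of 12.75 against 11.40. The first 4 principal components held 40.7%, 22.6%, 11.3% and 5.2% of the variance.

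The gene clr4 (SPBC428.08c) is the one named in the strain label. The feature carried reads in all 24 libraries. In clr4D-labelled cells its level was 337 ± 84.7 CPM at 0 h (SD, n = 2) and 385 ± 59.6 at 1 h, against 131 ± 58.2 and 108 ± 20.8 in wt. At 2, 4 and 10 h the levels in clr4D-labelled cells were 132 ± 20.6, 119 ± 10.0 and 129 ± 0.8, beside 110.2 ± 4.7, 118 ± 15.7 and 117 ± 12.6 in wt. At 24 h they were 188 ± 30.7 and 95.4 ± 8.2. The feature was called higher in clr4D-labelled cells at 0 h (log2 difference 1.36 ± 0.24 SE, adjusted p = 0.0155), at 1 h (1.89 ± 0.24, adjusted p = 0.000112) and at 24 h (0.98 ± 0.21, adjusted p = 0.00594), and was not called at 2, 4 or 10 h. The clr4 call at 0 h was lost without wt 0 h replicate 1 (0.94, adjusted p = 0.3) or clr4D 0 h replicate 2 (1.12, adjusted p = 0.11), and that at 24 h without wt 24 h replicate 1 (0.91, adjusted p = 0.0636) or clr4D 24 h replicate 1 (0.82, adjusted p = 0.0906). The reference annotation places this feature across meu6 on the opposite strand. Read counts per feature carry no position, so which part of the feature the reads come from is not known. For this reason the libraries are called clr4D-labelled below.

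**Figure D1:**
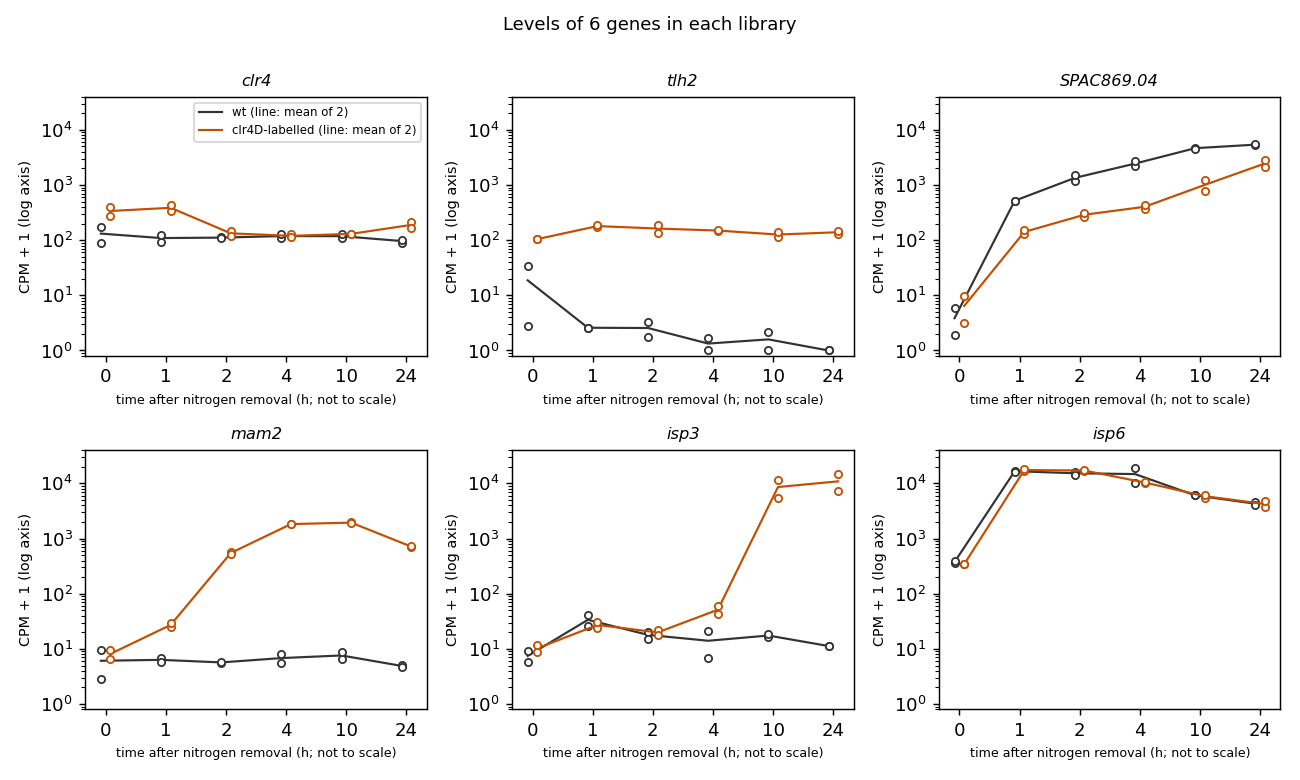
Levels of 6 genes (CPM + 1 on a log axis) against time after nitrogen removal in hours; points are single libraries and lines join the means of 2 libraries for wt and clr4D-labelled cells. tlh2 lies at 104 to 179 CPM in clr4D-labelled cells at the 6 times, isp3 reaches 10918 CPM in them at 24 h against 10.3 in wt, and isp6 stands higher at 1 h than at 0 h or 24 h in both strains.

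The comparison of wt cells at 1 h with 0 h shows the change within the first hour after the move to medium without nitrogen. No culture moved to fresh medium with nitrogen is among the libraries. Effects of nitrogen loss, of the transfer and of time therefore cannot be told apart in comparisons with 0 h. The protease gene isp6 rose from 375 ± 26.9 to 16671 ± 338 CPM (SD, n = 2; log2 difference 5.48 ± 0.32 SE, adjusted p = 9.86e-13). The xanthine dioxygenase gene xan1 rose from 30.2 ± 3.13 to 8961 ± 411 (8.22 ± 0.37, adjusted p = 9.53e-15), and the oligopeptide transporter gene isp4 rose by 5.21 ± 0.32 (adjusted p = 2.27e-12). Autophagy genes rose as a group: atg8, whose product builds the autophagosome membrane, went from 60.6 ± 22.8 to 247 ± 30.9 CPM (2.01 ± 0.28, adjusted p = 7.19e-06), and the kinase gene atg1 rose by 2.43 ± 0.21 (adjusted p = 9.76e-10). Genes for ribosomes fell, with rpl3002 going from 120 ± 19.8 to 6.75 ± 3.99 (-4.54 ± 0.31, adjusted p = 1.28e-11) and rpp203 from 398 ± 101 to 8.69 ± 3.26. The homocysteine synthase gene met17 fell from 2879 ± 512 to 35.8 ± 1.0 (-6.32 ± 0.30, adjusted p = 3.39e-14). The amidase gene SPAC869.01 went from 0 reads at 0 h, where the limit over the group is 1.55 CPM, to 98.3 ± 25.7. Among the landmarks, the vacuolar transporter gene fnx1 rose from 95.4 ± 0.89 to 448 ± 61.5, hsp9 from 1263 ± 173 to 5873 ± 32.5 and the gluconeogenesis gene fbp1 from 9.76 ± 0.23 to 193 ± 19.7.

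At 1 h 3026 genes were called in wt, 1502 higher and 1524 lower, of which 873 and 824 changed at least 2-fold. Of 24 autophagy genes 22 were higher, which held when adjusted over the list alone (median log2 difference 1.39, camera adjusted p = 2e-08, 0.0091 with an estimated correlation). Of 14 nitrogen starvation induced genes 11 were higher and 2 lower, with 12 and 2 when adjusted over the list alone (median 1.85, 3e-05, but 0.15 with an estimated correlation). Of 141 cytosolic ribosomal protein genes 139 were lower, as many as when adjusted over the list alone (median -3.01, adjusted p = 7e-40, but 0.19 with an estimated correlation). Ribosome biogenesis genes had 62 of 67 lower and 63 when adjusted over the list alone (median -1.44, adjusted p = 6e-20, 0.003 with an estimated correlation). Stress response genes had 19 of 26 higher (median 2.04, adjusted p = 1.5e-06, 0.16 with an estimated correlation), and amino acid biosynthesis genes 42 of 64 lower and 8 higher (median -0.82, adjusted p = 3.3e-07, 0.27 with an estimated correlation).

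At 24 h against 0 h in wt, the comparison asks what marks cells long after nitrogen loss. Among the largest rises, the formamidase-like gene SPAC869.04 went from 2.85 ± 2.76 to 5390 ± 236 CPM (SD, n = 2; log2 difference 10.98 ± 0.44 SE, adjusted p = 1.6e-15), and the urea transporter gene SPAC869.03c from 2.7 ± 1.27 to 3781 ± 159 (10.47 ± 0.38, adjusted p = 2.74e-16). The transcript nrg1 rose from 5.86 ± 1.9 to 2278 ± 224 (8.63 ± 0.28, adjusted p = 4.15e-17), and psu2, annotated as a beta-glucosidase, from 3.46 ± 1.49 to 1106 ± 132 (8.23 ± 0.49). Falls included met17 (-5.29 ± 0.28, adjusted p = 1.74e-13) and the biotin transporter gene vht1, from 2890 ± 730 to 102 ± 27.1 CPM (-4.82 ± 0.24, adjusted p = 9.61e-14). The arylsulfatase gene SPBPB10D8.02c went from 169 ± 29.6 CPM to 0 reads, where the limit is 0.53 CPM. swi6, the gene for a protein that binds methylated H3 lysine 9, fell from 140 ± 14.9 to 61.4 ± 3.55 (-1.20 ± 0.16, adjusted p = 9.94e-07). The fall of SPNCRNA.231 was not called without wt 0 h replicate 2.

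In wt 2961 genes were called at 24 h, 1342 higher and 1619 lower, after 3058, 2888 and 2856 at 2, 4 and 10 h. The split at 24 h depended on scaling. Library totals alone shifted the median of all genes by 0.493 (log2), and more genes were then called higher than lower. Ribosomal protein genes were still lower in 136 of 141 and 137 adjusted over the list alone (median -1.57, adjusted p = 4.7e-21, but 0.35 with an estimated correlation). Autophagy genes were higher in 20 of 24 (median 0.99, adjusted p = 4.3e-08, 0.0098 with an estimated correlation), and early meiosis genes in 14 of 26 (median 1.49, adjusted p = 0.00031, but 0.16 with an estimated correlation).

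In clr4D-labelled cells the same genes moved for the most part. Of 5664 genes, 2957, 2962, 2788, 3095 and 3096 were called at 1, 2, 4, 10 and 24 h against 0 h. At 1 h 2536 genes were called in both strains, and 2536 of them moved the same way. At 24 h this was 2428 of 2433. Across genes the log2 responses of the strains, which share no libraries, correlated at a Pearson r of 0.875, 0.865, 0.777, 0.701 and 0.777 and a Spearman rho of 0.881, 0.884, 0.814, 0.787 and 0.85 at the 5 times. Genes are not independent replicates, so no p is given. At 10 h 984 genes rose in both strains, where 365.1 would be shared by chance.

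The comparison of the strains at 0 h asks what the clr4D label means for cells that still have nitrogen. The helicase gene tlh2, which lies next to telomeres, stood at 104 ± 1.64 CPM against 17.7 ± 22.5 in wt (SD, n = 2; log2 difference 2.71 ± 0.49 SE, adjusted p = 0.0337). The small heat shock gene hsp16 stood at 318 ± 14.5 against 61.7 ± 24.7 (2.41 ± 0.32, adjusted p = 0.00293), and the Hsp70 gene ssa1 at 445 ± 64.4 against 178 ± 40.7 (1.32 ± 0.21, adjusted p = 0.0044). The lncRNAs SPNCRNA.231 and SPNCRNA.232 stood at 121 ± 60.7 and 147 ± 56.9 CPM against 14.7 ± 18.2 and 17.7 ± 22.5. The M-factor pheromone precursor gene mfm2 stood at 15.3 ± 0.04 against 2.7 ± 1.27 (2.53 ± 0.54, adjusted p = 0.0376). gdt1 (SPAC186.05c) and the helicase-like gene SPAC212.06c were at 17.4 ± 0.03 and 18.2 ± 2.06 CPM where wt had 1 and 2 reads. The cysteine transporter gene SPBPB10D8.01 was lower (-0.66 ± 0.13, adjusted p = 0.0325).

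At 0 h 13 genes were called, 11 higher, clr4 among them, and 2 lower, with 196 at an unadjusted p under 0.05. DESeq2 called 8 and limma-voom 9. Without wt 0 h replicate 1, 0 genes were called by edgeR (220 at an unadjusted p under 0.05), and the count was 5 without clr4D 0 h replicate 1, 4 without clr4D 0 h replicate 2 and 8 without wt 0 h replicate 2, of which 3, 4 and 7 were shared with the 13. A model of these 4 libraries alone called 17, of which 6 were shared. The call of hsp16 was lost only without wt 0 h replicate 1, that of tlh2 also without clr4D 0 h replicate 1 or replicate 2, and those of mfm2, SPAC212.06c, SPAPB24D3.07c and SPBPB10D8.01 with any single library of the 4 left out. In wt 0 h replicate 2 tlh2 was at 33.6 CPM from 28 reads, and in replicate 1 at 1.8 CPM. Subtelomeric genes had 3 of 51 higher and 1 lower, with 3 and 3 when adjusted over the list alone.

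At 1 and 2 h the comparison asks how the strains differ early in starvation. tlh2 was at 179 ± 11.7 and 161 ± 41.8 CPM against 1.58 and 1.55 in wt. By 2 h the genes of M-type cells stood apart: mam2, which encodes the receptor for the pheromone of P cells, was at 548 ± 17.8 CPM and the M-factor genes mfm1 and mfm2 at 459 ± 64 and 395 ± 4.71 (SD, n = 2), where wt stayed at or below 10.1 CPM at the times from 2 to 24 h. ste6, from the list of pheromone response and conjugation genes of both mating types, was higher by 2.26 ± 0.18 (SE, adjusted p = 4.64e-09). Histone genes were lower at 2 h, hht1 at 340 ± 37.2 against 845 ± 10.2 CPM (-1.31 ± 0.17, adjusted p = 1.16e-05) and hhf1 at 399 ± 27.6 against 981 ± 13.4 (-1.30 ± 0.17, adjusted p = 2.18e-05). At 1 h mam2 was at 26.2 ± 2.84 against 5.34 ± 0.78 (2.20 ± 0.34, adjusted p = 0.00038), a call lost without wt 1 h replicate 1.

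At 1 h 38 genes were called (26 higher) and at 2 h 88 (75 higher), with 386 and 447 at an unadjusted p under 0.05. The count at 1 h was 19 without wt 1 h replicate 1 and 25 without clr4D 1 h replicate 2. The count at 2 h was 52 without wt 2 h replicate 2 and 53 without clr4D 2 h replicate 2. All 8 M-cell genes were higher at 2 h, also when adjusted over the list alone (median 4.89, adjusted p = 1.2e-42, 3.3e-05 with an estimated correlation). Of the 4 P-cell genes 3 were higher (median 2.01, adjusted p = 5.8e-08, 0.0091 with an estimated correlation), and of 16 pheromone response genes 7, or 9 adjusted over the list alone (median 0.83, adjusted p = 2.9e-16, 0.005 with an estimated correlation). Histone genes had 3 of 11 lower, or 6 adjusted over the list alone (median -0.59, adjusted p = 9.8e-11, 0.031 with an estimated correlation).

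At 4 h the comparison follows the strains into prolonged starvation. M-cell genes were again higher, with mam2 at 1832 ± 15.8 CPM and mfm1 at 2296 ± 184 (SD, n = 2). map3, the receptor gene of P cells, was also higher, at 1690 ± 525 against 268 ± 11.2 (2.66 ± 0.26 SE, adjusted p = 1.49e-07). Of the meiosis genes, dmc1, which encodes a recombinase, was higher by 4.59 ± 0.74 (adjusted p = 0.000165), and mei3, whose product sets off meiosis, by 3.44 ± 0.69, a call lost without wt 4 h replicate 1 (2.36) and at an adjusted p of 0.0502 without clr4D 4 h replicate 1. The ammonium transporter gene amt1 was lower, at 799 ± 87.5 against 2284 ± 1549 CPM (-1.50 ± 0.28, adjusted p = 0.00109), and by -0.57 without wt 4 h replicate 2 (adjusted p = 0.0353). The glycolysis gene fba1 was lower on the mean of wt libraries that lay far apart, at 6985 ± 514 against 25213 ± 18888 CPM (-1.85 ± 0.37, adjusted p = 0.00142). SPAC869.04 was at 402 ± 41.3 against 2443 ± 332. Subtelomeric genes went both ways, 10 of 51 higher and 12 lower, with a median of -0.11 and a mean of 0.47.

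At 4 h 850 genes were called, 294 higher and 556 lower, and scaling by library totals alone turned this into 565 higher and 185 lower, upper quartile scaling into 367 and 400. A model of these 4 libraries alone called 92, with 86 higher and 6 lower. The count was 1325 without wt 4 h replicate 1 (430 higher and 895 lower), 396 without wt 4 h replicate 2 (225 and 171), 261 without clr4D 4 h replicate 1 (151 and 110) and 533 without clr4D 4 h replicate 2 (219 and 314). Ribosomal protein genes had 107 of 141 lower and 128 adjusted over the list alone (median -1.08, adjusted p = 5.2e-27, but 0.28 with an estimated correlation). Without wt 0 h replicate 2 and wt 4 h replicate 2, 1 of them was lower, the call of fba1 was lost, and 375 genes were called, 354 of them shared with the 850. Early meiosis genes had 21 of 26 higher and 23 adjusted over the list alone (median 1.99, adjusted p = 7.9e-16, 0.0075 with an estimated correlation). Nitrogen starvation induced genes had 10 of 14 lower, as many as adjusted over the list alone (median -0.75, adjusted p = 1.9e-07, 0.068 with an estimated correlation), and 5 without those libraries. Glycolysis genes had 12 of 17 lower, or 15 lower and 1 higher adjusted over the list alone (median -1.03, adjusted p = 5.7e-07, but 0.27 with an estimated correlation), and 3 lower without those libraries (median -0.40).

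**Figure D2:**
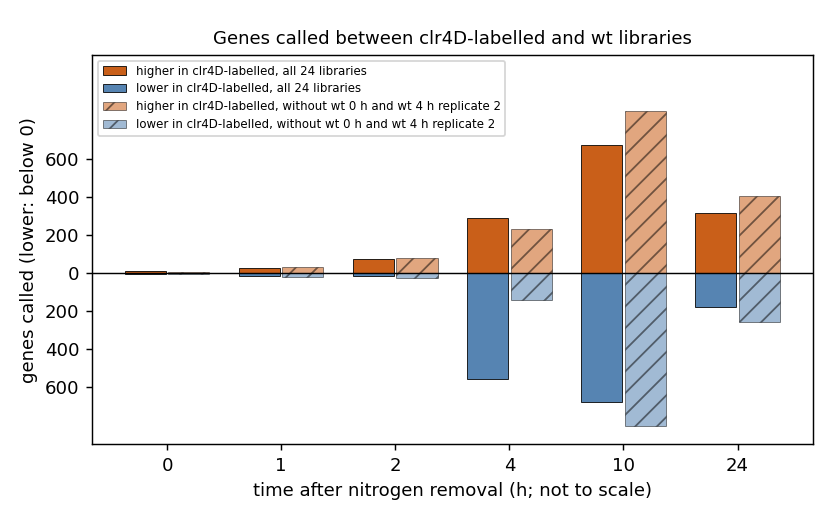
Number of genes called between clr4D-labelled and wt libraries (bars above 0 are higher in clr4D-labelled, bars below 0 are lower) against hours after nitrogen removal, from all 24 libraries (plain bars) and without replicate 2 of wt 0 h and wt 4 h (hatched bars). At 4 h 556 lower calls become 139, and at 10 h 677 higher calls become 854.

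At 10 h the comparison shows the widest difference between the strains. Among the genes higher in clr4D-labelled cells were spore and meiosis genes: isp3, a spore wall gene, was at 8607 ± 4494 CPM against 16.5 ± 1.69 in wt (SD, n = 2; 9.05 ± 0.50 SE, adjusted p = 2.3e-11), and meu17, a spore-related glucan hydrolase gene, at 642 ± 404 against 1.5 ± 1.01. mei4, the transcription factor gene of middle meiosis, was at 140 ± 20.4 against 38.4 ± 2.07 (1.89 ± 0.22, adjusted p = 5.16e-07). mei3 was at 48.2 ± 6.87 CPM where wt had 0 reads, with a limit of 0.87. Mating genes of both types were higher, mam2 at 1949 ± 33.6 CPM, map2, the gene of the P-factor pheromone, at 3333 ± 248 against 407 ± 43.3 (3.04 ± 0.28, adjusted p = 2.13e-08), and the agglutinin gene map4 at 1088 ± 198 against 54.1 ± 14.3 (4.39 ± 0.37, adjusted p = 2.95e-07). ste11, the master regulator gene of mating, was at 884 ± 103 against 389 ± 36 (1.19 ± 0.33, adjusted p = 0.0148), a call lost without wt 10 h replicate 1, clr4D 10 h replicate 1 or wt 10 h replicate 2. mei2, for an RNA-binding protein that meiosis needs, was at 4591 ± 613 against 1783 ± 296 (1.37 ± 0.32, adjusted p = 0.00287), a call lost without wt 10 h replicate 1. The proline permease gene put4 was lower, at 781 ± 77.3 against 2049 ± 166 (-1.39 ± 0.18, adjusted p = 1.94e-06).

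At 10 h 1354 genes were called, 677 higher and 677 lower, and 727 and 461 under library totals alone. The count was 722 without wt 10 h replicate 1 and 713 without clr4D 10 h replicate 1. Middle and late meiosis genes had 28 of 30 higher and 1 lower, also adjusted over the list alone (median 5.03, adjusted p = 1.3e-28, 0.008 with an estimated correlation). The lower member was atd3 (meu8), an aldehyde dehydrogenase gene. Early meiosis genes had 25 of 26 higher and mcp7 lower (median 2.49, adjusted p = 2.4e-19, 0.0043 with an estimated correlation). M-cell genes were higher in 8 of 8 (median 6.13, adjusted p = 1.8e-17, 0.00081 with an estimated correlation), and P-cell genes in 3 of 4, all but sxa1 (median 2.95, adjusted p = 0.00096, but 0.081 with an estimated correlation). Pheromone response genes were higher in 13 of 16 and 15 adjusted over the list alone (median 1.28, adjusted p = 5.7e-12, 0.0091 with an estimated correlation). Amino acid biosynthesis genes had 32 of 64 lower and 2 higher, or 42 and 2 adjusted over the list alone (median -0.51, adjusted p = 2.4e-10, but 0.18 with an estimated correlation). Ribosomal protein genes had 49 of 141 lower and 85 adjusted over the list alone (median -0.78, adjusted p = 7.4e-17, but 0.42 with an estimated correlation), and 111 without wt 0 h replicate 2 and wt 4 h replicate 2 (median -0.75). Nitrogen starvation induced genes had 9 of 14 lower and 11 adjusted over the list alone (median -0.73, adjusted p = 1.1e-06, but 0.09 with an estimated correlation), and 10 without those 2 libraries (median -0.70). Ribosome biogenesis genes had 23 of 67 lower and 31 adjusted over the list alone (median -0.38, adjusted p = 3.3e-08, 0.026 with an estimated correlation), with cbf5 lower by -0.88 ± 0.16 (adjusted p = 0.00022).

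**Figure D3:**
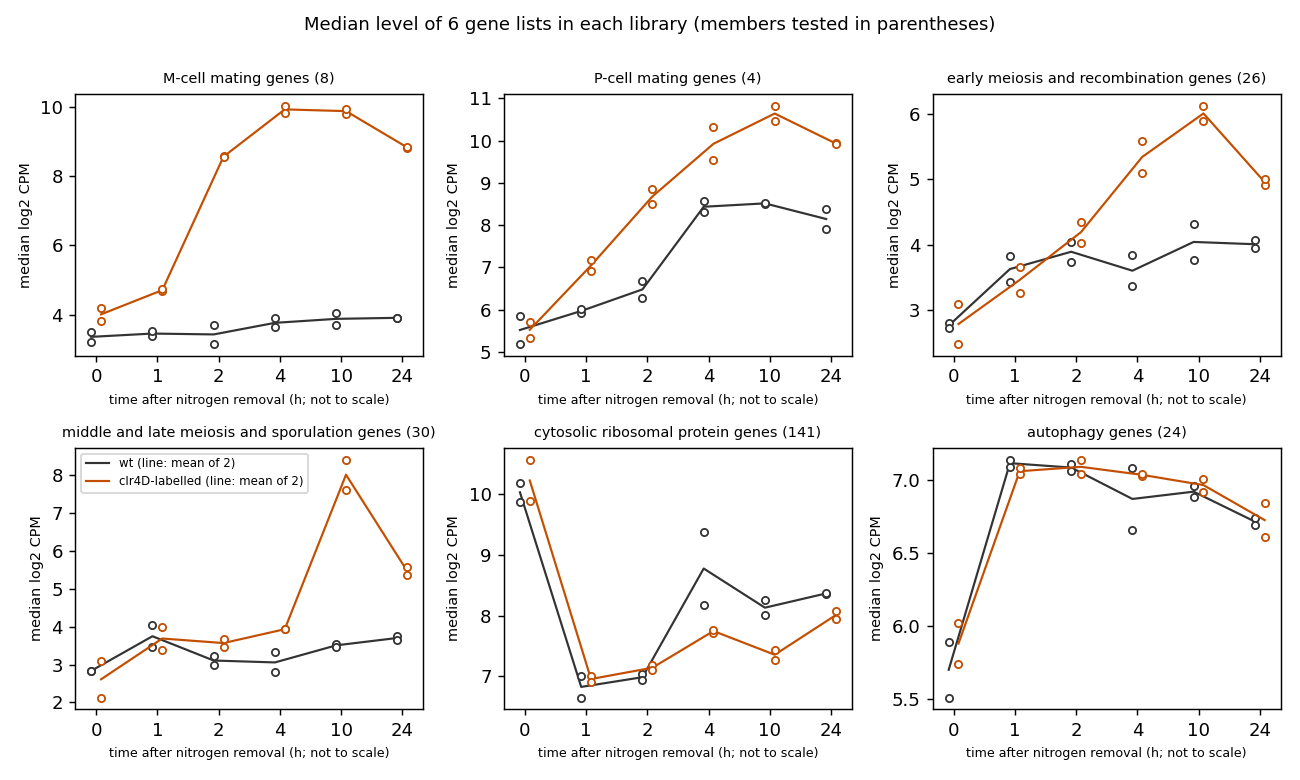
Median log2 CPM of 6 gene lists against time after nitrogen removal in hours; points are single libraries and lines join the means of 2 libraries for wt and clr4D-labelled cells. M-cell and meiosis lists part between the strains (median log2 differences of 6.13 and 5.03 at 10 h for the M-cell and the middle and late meiosis lists), while the 24 autophagy genes have a median log2 difference of 0.14 at 10 h.

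At 24 h the comparison asks how the strains differ in long starvation. isp3 was at 10918 ± 5217 CPM against 10.3 ± 0.04 (SD, n = 2; log2 difference 10.04 ± 0.51 SE, adjusted p = 1.12e-11). The M-factor gene mfm3 was at 415 ± 59.4 against 1.66 ± 1.41 (7.95 ± 0.30, adjusted p = 6.43e-15), and meu6, a gene of meiotic cells, at 344 ± 133 against 1.43 ± 0.13 (7.84 ± 0.61, adjusted p = 7.06e-07). tlh2 stood at 138 ± 10.3 CPM where wt had 0 reads, with a limit of 0.53 CPM, as did SPNCRNA.364 at 22.3 ± 0.04 and the subtelomeric gene SPAC186.06 at 18.3 ± 2.28. hsp16 was at 318 ± 128 against 55.2 ± 2.88 (2.52 ± 0.27, adjusted p = 7.05e-06). SPAC869.01 was lower, at 1.43 ± 1.41 CPM against 55.7 ± 12.6 (-5.26 ± 0.45, adjusted p = 5.25e-08). The poly(A)-binding protein gene nab3 was lower at 43.2 ± 2.1 against 133 ± 11.7 (-1.62 ± 0.21, adjusted p = 7.28e-06), and the amino acid permease gene aat1 at 56.8 ± 15.1 against 155 ± 0.46 (-1.46 ± 0.18, adjusted p = 3.18e-06). The thiamine synthesis gene nmt1 was at 1758 ± 213 against 4570 ± 763 (-1.38 ± 0.32, adjusted p = 0.00657), a call lost without clr4D 24 h replicate 1 or wt 24 h replicate 2. The same 2 libraries decide the call of atg8, which was higher by 0.94 ± 0.23 (adjusted p = 0.0138). psu2 was lower by -1.21 ± 0.26 (adjusted p = 0.00702), a call lost without wt 24 h replicate 2 or clr4D 24 h replicate 2 and with DESeq2.

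At 24 h 498 genes were called, 319 higher and 179 lower, of which 228 and 14 differed at least 2-fold. The split was 321 and 54 under library totals alone, 351 and 106 under the DESeq2 size factors and 363 and 108 under upper quartile scaling. The count was 319 without wt 24 h replicate 1, 229 without clr4D 24 h replicate 1 and 199 without wt 24 h replicate 2. M-cell genes were higher in 8 of 8 (median 4.99, adjusted p = 5.9e-28, 0.00019 with an estimated correlation), middle and late meiosis genes in 18 of 30 (median 1.79, adjusted p = 1.7e-20, 0.013 with an estimated correlation) and early meiosis genes in 14 of 26, with 22 adjusted over the list alone (median 1.23, adjusted p = 3e-14, 0.0091 with an estimated correlation). Ribosomal protein genes had 3 of 141 lower, 15 without wt 0 h replicate 2 and wt 4 h replicate 2, and 0 adjusted over the list alone (median -0.40, adjusted p = 2.5e-08, but 0.64 with an estimated correlation). Stress response genes had 6 of 26 higher and 10 adjusted over the list alone (median 0.40, adjusted p = 9.3e-07, but 0.15 with an estimated correlation). Subtelomeric genes had 15 of 51 higher and 8 lower, with 17 and 9 adjusted over the list alone (median 0.34, adjusted p = 0.00012, but 0.085 with an estimated correlation), a list that includes isp3 through its systematic name. Of 675 lncRNAs tested 76 (11.3%) were higher and 3 (0.4%) lower, against 235 (4.8%) and 175 (3.5%) of 4944 coding genes.

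Over the mean of the 6 times, the comparison averages the strain difference and does not show at which times a gene differs. The model treats the libraries of different times as independent. The labels do not say whether the 6 times of a replicate come from the same culture. If they do, the SE and p of this mean may be too small. tlh2 was higher by 6.97 ± 0.27 (log2, SE, adjusted p = 3.76e-11), SPNCRNA.232 by 7.13 ± 0.27 (adjusted p = 4.38e-11), mfm2 by 5.94 ± 0.16 (adjusted p = 1.59e-18) and mfm1 by 5.79 ± 0.30 (adjusted p = 1.03e-12). The size of such differences depends on the default prior count of the edgeR fit where wt has 0 to 3 reads. That prior is not the prior count of 2 used for log2 CPM. Lower were the urea transporter gene SPAC869.03c by -1.64 ± 0.22 (adjusted p = 5.65e-06), SPAC869.04 by -1.58 ± 0.24 (adjusted p = 3.15e-05) and yhb1, for a nitric oxide dioxygenase, by -1.06 ± 0.08 (adjusted p = 1.93e-10). Also lower were nrg1, by -1.07 ± 0.13 (adjusted p = 8.92e-07), and the malic enzyme gene mae2, by -0.79 ± 0.12 (adjusted p = 3.34e-05).

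Over this mean 1389 genes were called, 583 higher and 806 lower, of which 160 and 6 differed at least 2-fold, and under library totals alone 791 were higher and 334 lower, under upper quartile scaling 731 and 537. At all 6 single times 9 genes were higher, which are tlh2, gdt1, SPAC212.06c, mfm2, hsp16, SPAPB24D3.07c, SPNCRNA.231, SPNCRNA.232 and SPBC23G7.10c, the last chosen after its values were seen. SPAC869.01, SPAC869.03c and SPAC869.04 were lower at 5 times. Subtelomeric genes had 16 of 51 higher and 10 lower, so that their median was 0.00 and their mean 0.85 (camera adjusted p = 0.2). The transcript of tlh1, a near-identical copy of tlh2, had 2.09 to 7.01 CPM in clr4D-labelled cells and at most 1.2 in wt, and reads that fit both copies were not counted.

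The difference between the strains in the change from 0 h to 24 h asks whether the change after the move to medium without nitrogen is another in clr4D-labelled cells. The serine carboxypeptidase gene sxa2, which answers to pheromone, had a larger rise in them by 3.58 ± 0.41 (log2, SE, adjusted p = 1.3e-05). The change of aat1 was lower in them by -1.64 ± 0.25 (adjusted p = 0.000428). SPBPB10D8.02c fell in wt from 169 ± 29.6 CPM to 0 and in clr4D-labelled cells from 86.9 ± 18 to 7.1 ± 1.12 (SD, n = 2; adjusted p = 0.000112 for the difference). These calls, with that of SPAPB24D3.07c, held with each library left out in turn. isp3 differed by 9.68 ± 1.27 (adjusted p = 0.0002) and lost its call without wt 0 h replicate 1. mam2 differed by 7.04 ± 0.71 (adjusted p = 2.15e-06) and tlh2 by 8.10 ± 1.57 (adjusted p = 0.0187), and both lost their calls without wt 0 h replicate 2. At 24 h against 0 h 55 genes differed in their change, 47 with a higher and 8 with a lower change in clr4D-labelled cells, and 24 without wt 0 h replicate 2 and 36 without clr4D 0 h replicate 2.

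The F test for any difference in the course over the 6 times called 389 genes, 366 of 4944 coding and 21 of 675 lncRNA. The count was 1148 without wt 4 h replicate 1, 587 without wt 4 h replicate 2, 191 without wt 10 h replicate 1 and 217 without clr4D 10 h replicate 1. Among them were 8 of 8 M-cell genes, 3 of 4 P-cell genes, 16 of 26 early and 23 of 30 middle and late meiosis genes and 11 of 141 ribosomal protein genes. From the autophagy list, none of whose members was in that set, 1 member was called between the strains at 4 h and 1 at 24 h. Without wt 0 h replicate 2 and wt 4 h replicate 2, 4 members were higher at 10 h (median 0.17) and 1 at 24 h. With all libraries these were atg1, lower at 4 h (-0.55 ± 0.19, adjusted p = 0.0485), a call lost under each other scaling, with DESeq2, and without clr4D 4 h replicate 1, wt 4 h replicate 2 or clr4D 4 h replicate 2, and atg8, higher at 24 h. The gene isp6 was not called between the strains at any time, with 4288 ± 385 CPM in wt and 4229 ± 714 in clr4D-labelled cells at 24 h (SD, n = 2).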

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

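The test of other splits of the libraries was chosen before its result was seen, and the other 8 tests in this part were chosen after. Some of those 8 were changed after a value was seen: the test of a mixture in wt 0 h replicate 2 was run in 2 forms, the test of exchanged labels was moved to tlh2, and the test of meu6 reads took the place of a test that counts per feature cannot carry.

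What sets the following results apart is that the change with time differed between the strains, by a test of that difference. The F test over the 6 times called 389 genes, and the change from 0 h to 24 h differed for 55. The change was higher in clr4D-labelled cells for isp3 (9.68 on the log2 scale), tlh2 (8.10), SPBPB10D8.02c (7.45), mam2 (7.04), the lncRNA SPNCRNA.573 (6.43), mfm2 (4.26), map4 (4.24), SPAPB24D3.07c (4.08), mug4 (3.75) and sxa2 (3.58). For genes with 0 to 3 reads in a group, such as tlh2 in wt at 24 h, this fitted size depends on the default prior count of the edgeR fit. The change was lower for aat1 (-1.64), nog2 (-1.11), SPBC19C7.04c (-1.10), htr11 (-1.09), mfs3 (-1.08), zpr1 (-1.08), SPAC513.07 (-1.06) and adh4 (-1.05). Without wt 0 h replicate 2 the count was 24, and tlh2, mam2, mfm2, map4, mug4, SPNCRNA.573 and the listed genes with a lower change other than aat1 were not called. Without clr4D 0 h replicate 2 the count was 36, and without wt 0 h replicate 1 isp3 was not called.

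Among the lists, M-cell genes had a median difference in change of 3.92 (adjusted p = 2.6e-25, 0.00022 with an estimated correlation), P-cell genes 2.11 (4e-05, 0.03), pheromone response genes 1.03 (6.4e-11, 0.01), early meiosis genes 0.98 (1.4e-09, 0.022) and middle and late meiosis genes 1.39 (4.7e-17, 0.023). Ribosome biogenesis genes had -0.31 (3.1e-07, 0.036). The other lists passed only with the preset correlation. They were subtelomeric genes at 0.18 (adjusted p = 0.0026, 0.17 with an estimated correlation), nitrogen starvation induced genes at -0.41 (0.00077, 0.21), ribosomal protein genes at -0.64 (5.3e-14, 0.48), stress response genes at 0.21 (0.011, 0.44), MBF targets at 0.40 (7.1e-05, 0.15), wtf genes at 0.42 (0.021, 0.46), glycolysis genes at -0.44 (0.0076, 0.6) and amino acid biosynthesis genes at -0.31 (2.5e-06, 0.3).

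Chance was tested for the difference over the mean of the 6 times by regrouping the 4 libraries of each time at random into pairs. The real grouping called 1389 genes and the highest of the other splits 514. Of the 100 splits 1, the real one, gave as many, which argues against a random grouping as the source of this count. Splits that mix the strains take the strain difference into their spread, which lowers their counts. The test cannot tell the strain from anything else that the libraries of a strain share.

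In clr4D-labelled libraries, most genes of the M-cell list were called above wt from 2 h, of the early meiosis list from 4 h and of the middle and late meiosis list at 10 and 24 h, although the strain carries a P-type label. Single M-cell genes were called earlier, mfm2 at 0 h and mam2 at 1 h. A strain of M type in place of the P-type strain stays open. The smallest median log2 difference of the P-cell genes over 2 to 24 h was 2.01 above wt. This argues against an M-type strain that expresses no P-cell genes. An M-type strain without silencing might express them, so the values cannot decide. M-type cells with intact silencing mixed into the cultures cannot be told apart from the other explanations. The transcripts followed were the 21 called higher in clr4D-labelled libraries at 5 or 6 times. They had a median log2 change of 1.11 from 0 h to 10 h. The set was chosen by these calls alone and held the M-cell genes mam2 and mfm2, so its rise is partly the pattern in question. Without libraries of M-type cells the share such cells would need is not known. M-cell and P-cell genes were both above wt in the same clr4D-labelled libraries. The smaller of the M-cell and P-cell medians at 4 and 10 h lay 2.29 above wt, which restates what raised the question. Whether the same cells expressed genes of both types stays open, because these libraries do not separate cells. The features mat1-Mc, mat1-Mi, mat3-Mc and mat3-Mi had 0 reads in each library. Reads that align to several places were not counted, and silent or absent cassettes would give 0 as well, so these zeros decide nothing. What would bring about expression of both types, such as loss of silencing at the cassettes, was not tested. Whether meiosis took place in haploid cells or after mating was not tested.

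Reads lay on the clr4 feature in libraries labelled as its deletion. Exchanged strain labels are argued against by tlh2: the lowest clr4D-labelled library had 102.4 CPM and the highest wt library 33.6, a ratio of 3.05. Wild-type cells mixed into the cultures are excluded as the whole cause, because the lowest clr4D-labelled library exceeded the highest wt library in clr4 by a ratio of 1.62 at 0 h and 2.79 at 1 h. Reads of meu6, which overlaps the feature on the opposite strand, are argued against too. In clr4D-labelled libraries meu6 rose from 4.2 ± 2.9 to 714 ± 394 CPM (SD, n = 2) from 0 h to 10 h, by 69.4-fold from the highest to the lowest library, while the highest clr4 level at 10 h was 0.47 of the lowest at 0 h. A part of the gene left beside the marker, transcribed from its own or the marker's promoter, may give such reads, and stays open because counts per feature carry no position. No biological explanation was tested.

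In wt 0 h replicate 2, some transcripts that are low in other wt libraries, such as tlh2, SPNCRNA.231 and SPNCRNA.232, stood at intermediate levels. tlh2 was at 33.6 CPM there, 31.3% of the way from replicate 1 to the clr4D-labelled 0 h mean. SPAPB24D3.07c was not raised, at 22.8 CPM against 23.5 in replicate 1. clr4, which is not low in other wt libraries, was at 172 CPM against 89.3 in replicate 1. RNA of a clr4D-labelled culture after nitrogen removal is argued against: tlh2 would need a share of 17.9%, while isp6, fnx1, hsp9 and fbp1 allow at most 0.55%. RNA of the clr4D-labelled 0 h cultures mixed into the library may be a source. The 9 transcripts tested had a fitted common share of 20.5%, with single shares from -1.5% to 40.2%. A departure from 1 common share at least as large as that seen came up in a fraction of 0.307 of simulated sets of the 0 h libraries. In wt 0 h replicate 2, gdt1 and SPAC212.06c had 1 read each and mfm2 had 3, so unequal shares could be missed. The test therefore neither excludes a mixture nor lends it support. Incomplete silencing in that wt culture is a biological alternative that stays open and was not tested.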

How the results depend on the processing

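The fit without wt 0 h replicate 2 and wt 4 h replicate 2 was chosen after seeing the data; the other alternatives were set before. For counts of genes called, 304 of 334 alternatives lay within 1.5 times the reported count, and for list tests 2627 of 2898 kept direction and side of the threshold (fry, a different kind of test, 339 of 414). Of 6999 alternatives for 493 called values of named genes, 6399 kept both, and 2 reversed under library totals alone. Calls were lost in 441 with a library out, 56 with both libraries named above out, 37 under library totals alone, 34 with DESeq2, 10 with limma-voom, 10 under upper quartile scaling, 8 under the DESeq2 size factors and 2 with the replicate block. Leaving out each library in turn gave 0 to 8 genes at 0 h between the strains (0 without wt 0 h replicate 1, with 220 at an unadjusted p under 0.05), 19 to 40 at 1 h, 52 to 75 at 2 h, 261 to 1325 at 4 h, 713 to 1092 at 10 h, 199 to 347 at 24 h, 191 to 1148 for the F test over time and 24 to 52 for the strain difference in change at 24 h. With a library out its group has 1 library, which is assumed to vary like the other groups. DESeq2 called 8 genes at 0 h. A model of the compared groups alone called 64 at 1 h, 92 at 4 h (86 higher, 6 lower), 861 at 24 h and 1805 for wt 4 h against 0 h, with a spread taken from 4 libraries. Without both libraries named above, 375 genes were called at 4 h and 1659 at 10 h, of which 354 and 1335 were shared with the reported calls. Camera called 212 of 414 list tests, and 59 with an estimated correlation. A replicate block, which treats equal replicate numbers as a pairing common to both strains, called 936 genes at 4 h, 1523 at 10 h and 605 at 24 h. The block moved no count by more than 1.5 times. It cannot represent a culture shared over time within a strain.

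Library totals alone shifted the median of all genes between the strains by 0.285 at 4 h, 0.116 at 10 h and 0.113 at 24 h (log2), and against 0 h by up to 0.493 in wt and 0.592 in clr4D-labelled cells. Under it the medians turned sign for ribosome biogenesis genes between the strains at 4 h (-0.16 to 0.13), and for proteasome genes at 24 h against 0 h in wt (-0.33 to 0.17) and in clr4D-labelled cells (-0.28 to 0.34). At 24 h against 0 h 1342 higher and 1619 lower genes in wt became 2336 and 718, and in clr4D-labelled cells 1439 and 1657 became 2757 and 679. The calls of ras1 and byr1 in wt at 24 h against 0 h reversed to 0.028 and 0.081 under it, where the shift of the median is larger than these values. For the other alternatives above that moved a count, the cause was not tested beyond the number of libraries left. A list of subtelomeric genes by distance from the chromosome end was not run, because the reference is of another build. Depth limits genes near the limit of 0.53 to 1.97 CPM per group, where a difference was not detectable.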

Other observations

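Some histone genes and single cell cycle genes differed between the strains during starvation. The histone H3 and H4 genes hht1 and hhf1 were lower in clr4D-labelled cells at 1 h, by -1.15 ± 0.17 and -0.98 ± 0.17 (log2, SE; adjusted p = 0.000231 and 0.00233), and at 2 h. The list of 11 histone genes, 9 of which rose in wt by 1 h (median 1.34, adjusted p = 0.00024, 0.2 with an estimated correlation), was not called between the strains by camera at 24 h. Within the list cnp1, for the centromeric histone H3, was higher at 4 h with 41.8 ± 2.58 against 7.27 ± 3.9 CPM (SD, n = 2, log2 difference 2.15 ± 0.33, adjusted p = 8.32e-05). Targets of the S phase factor MBF were higher in 11 of 19 and lower in 1 at 4 h, with 13 and 1 adjusted over the list alone (median 0.65, adjusted p = 1.1e-06, but 0.082 with an estimated correlation). At 10 h the mitotic inhibitor gene mik1 was at 213 ± 51.7 against 22.8 ± 2.22 CPM (3.27 ± 0.21, adjusted p = 2.47e-11) and the cyclin gene cig2 at 506 ± 41.2 against 134 ± 7.79 (1.93 ± 0.17, adjusted p = 7.01e-09). rep1, an activator gene of MBF in meiosis, was at 213 ± 25.3 against 20.4 ± 2.25 (3.35 ± 0.19, adjusted p = 1.44e-12).

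The genes next to the mating-type locus mat1 in the reference, SPBC23G7.10c, annotated as a flavin oxidoreductase gene, and the DNA glycosylase gene mag2, were chosen after their values were seen. Over the 6 times SPBC23G7.10c stood at 0 to 3.19 CPM in the 12 wt libraries, with 0 in both at 0 h. In clr4D-labelled cells it stood at 8.36, 60.6, 89.0, 53.3, 22.9 and 13.6 CPM in replicate 1 and at 10.9, 34.7, 73.9, 55.9, 21.3 and 12.3 in replicate 2. The call of SPBC23G7.10c at 0 h was lost with each library of those groups left out, with DESeq2 and with limma-voom. mag2 was higher in clr4D-labelled cells at the 5 times after nitrogen removal, a call lost at 10 h without wt 10 h replicate 1 (2.17, adjusted p = 0.108). Among lncRNAs called over the mean of the 6 times, more were higher than lower in clr4D-labelled cells: 102 of the 675 tested (15.1%) were higher and 13 (1.9%) lower, against 469 and 792 of 4944 coding genes. The split of all genes over this mean turned under library totals alone, as given above. The filter kept 675 of 1382 lncRNAs and 4944 of 5103 coding genes. A transcript near the detection limit in wt can hardly be called lower, which limits this contrast of classes.

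Iron uptake genes were higher in 7 of 12 and lower in 1 at 10 h, with 8 and 1 adjusted over the list alone (median 0.68, adjusted p = 0.0064, but 0.22 with an estimated correlation). The ferric reductase gene frp1 was at 42.5 ± 26.7 against 4.01 ± 0.98 CPM (SD, n = 2; 3.33 ± 0.46, adjusted p = 5.92e-06). The wtf genes, a family that includes spore killers expressed in meiosis, were higher in 12 of 20 and lower in 1 at 10 h, also adjusted over the list alone (median 1.10, adjusted p = 0.00038, but 0.25 with an estimated correlation). Of these, wtf18 was at 38.9 ± 19.3 against 8.74 ± 0.15. Of 27 mitosis and cell separation genes 6 were higher at 10 h, among them the septum glucanase gene agn1 at 295 ± 6.94 against 90.7 ± 7.82 (1.72 ± 0.30, adjusted p = 0.00054), while the median was -0.16 and the mean 0.06 (camera adjusted p = 0.99). Of 10 phosphate response genes 1 was lower at 10 h, vtc4 at 351 ± 37.9 against 705 ± 11.8 (-1.01 ± 0.17, adjusted p = 6.22e-05), with 3 lower and 1 higher adjusted over the list alone (median -0.27, adjusted p = 0.15). Glycolysis genes were lower in 4 of 17 and higher in 1 at 10 h, with 8 and 1 adjusted over the list alone (median -0.64, adjusted p = 0.0041, but 0.57 with an estimated correlation).

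Other lists showed little between the strains at 10 h. Of 24 heterochromatin and RNAi factors 1 was higher, mit1 (0.47 ± 0.14, adjusted p = 0.0176), a call lost with each library of the groups left out, and 0 were called adjusted over the list alone. Of 31 proteasome genes 1 was higher, pre9 (0.42 ± 0.13, adjusted p = 0.0235), and of 23 kinetochore genes 2 were higher, fta2 (0.72 ± 0.26, adjusted p = 0.0468) and mal2 (0.49 ± 0.17, adjusted p = 0.0426). Of 13 Tf2 retrotransposons 2 had enough reads to test, and neither was called. In the amino acid biosynthesis list, trp663 and trp1322 matched by name but are channel-type genes. The mitochondrial list matched 0 of 11 names.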
